A study of Mus musculus with 4 samples.

How the data were processed

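The samples were 4 RNA-seq libraries of mouse MLL-AF9 leukaemic cells, 2 from cells treated with EtOH for 72 h and 2 from cells treated with OHT for 72 h. RNA was isolated with an RNeasy kit and libraries were made with version 2 of the TruSeq RNA kit, per the labels' protocols; that kit does not mark strand. The submitters' processing notes name TopHat, DESeq and genome build mm9, without versions or roles, and do not name the program that counted reads.

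The only processed file is the authors' own comparison of OHT with EtOH, with 18061 RefSeq transcripts of 16545 symbols and no values per sample. The signal columns, per the file headers the base means of the 2 groups, are averages of normalised reads over the 2 libraries of a group as the values show. The deposited ratio column is the OHT mean divided by the EtOH mean, and the deposited log2 column is the log2 of that ratio. The deposited p-value columns hold a p per transcript and an adjusted p, which equals a Benjamini-Hochberg adjustment over all transcripts of the table to within 2.63e-06. The settings of the authors' test are not stated.

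The design written before the data were examined assumed read counts per sample, and its stated fallback for a table of the authors' own comparison was used. Calls are transcripts with an adjusted p under 0.05 in the authors' deposited table, and no test was put in its place. Each symbol in a gene list stands for its transcript with the highest mean. Of the symbols, 1297 had more than 1 transcript, and reads shared between them may have been lost or split: the median EtOH mean was 53.5 for symbols with 1 transcript and 22.9, summed over transcripts, for symbols with several. Reads of overlapping genes, of antisense partners and of near-identical copies cannot be told apart here. No coordinates are given, since the reference tables at hand follow GRCm38.p6 and not mm9.

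Every group mean solved to whole reads of 2 libraries, with 1 read added to each library's count before division by a size factor. The solution was unique for 100% of the 18061 transcripts in both groups. When means were moved by up to 0.1%, 0.0775% of EtOH and 0.116% of OHT means still solved, and 0.809% and 1.17% of means of at least 1000. In a test on simulated data 100% of 4000 simulated means were solved. The solved libraries are called A and B within each group. They had size factors of 1.206 and 0.768 for EtOH and 1.191 and 0.896 for OHT and totals of 6255320, 3841243, 5687967 and 4509718 reads, and no file links them to the replicate numbers of the labels. Counts of at most 3 reads in a group are taken as the floor, and exact 95% intervals of read ratios cover counting error only.

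The solved reads were fitted by group with limma-voom, for the 11338 transcripts with at least 10 reads in 2 libraries, using the solved size factors and Benjamini-Hochberg adjustment. This fit, with 2 residual degrees of freedom, was chosen after seeing the data, as were its versions with other scalings and filters, without 1 library at a time, and with 1 transcript per symbol. On simulated reads for 11302 transcripts of this comparison, the fit recovered 2%, 22%, 94% and 100% of 1.5-fold, 2-fold, 4-fold and 8-fold changes, 50 of each. Of its 115 calls there, 5.22% were unchanged transcripts. The simulated dispersion of 0.05 was set and not estimated from these data.

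Before the data were examined, 35 gene lists were fixed, with cell type markers and lists read as signs of RNA quality among them. The median log2 fold change of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list outside their central 95% counts as moved. On simulated lists of this comparison, with 16545 genes and 200 lists, 5.0% of unchanged lists and 99.5% of lists shifted by a log2 of 1 lay outside. Fold changes were permuted over genes there, so this check does not cover genes that vary together. Camera with its preset correlation of 0.01, camera with an estimated correlation, and fry were run on the solved reads after the data were seen, with Benjamini-Hochberg adjustment over the lists. The columns held no samples outside the series.

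The 109 named transcripts follow a rule set before the data were examined. It takes Rnf2, Ring1 and Cdkn2a, then the 12 largest rises and 12 largest falls among calls with both OHT libraries on one side of both EtOH libraries and a mean of at least 100 in the higher group. Symbols of predicted or unnamed genes are left out, and some transcripts that the rule takes are not reported here. It then takes up to 4 members of each list with the smallest adjusted p among calls, or the 2 with the highest mean where none was called. Of the names outside the rule, Lhx1, Lhx2, Otx1, C1qa, C1qc, Irf8, Klf4, Lgmn, Maf and Rtp4 are further calls of a list, Lmo2 was called over its list alone, and Meis1, Hoxa9, Cdkn1a and others called only by limma-voom (Ltf, Pax8, Six4, Hmgb3, Dot1l, Birc3, Bmf, Gadd45a, Bbc3, Rrm2b, Apoe, Prg3, Prss34, Ier2, Klf2, Insig1, Nsdhl, Hist1h1d and Hist1h1e) were singled out; all were chosen after their values were seen.

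Alternatives set beforehand and run were a stricter adjusted p of 0.01, a 2-fold minimum, minimum means of 10 and 100, and random lists not matched on mean. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.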

Results

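The data are RNA-seq profiles of mouse MLL-AF9 leukaemic cells, a myeloid leukaemia model driven by a fusion of the histone methyltransferase gene MLL with AF9. The cells came from mouse bone marrow and were grown in liquid culture. They carried floxed Rnf2 on a background lacking Ring1 and Cdkn2a. Rnf2 and Ring1 encode RING1B and RING1A, the ubiquitin ligases of Polycomb repressive complex 1 (PRC1), which modifies histone H2A at silenced genes. Cells were treated for 72 h with OHT (in common usage hydroxytamoxifen, the ligand of recombinases used to delete floxed alleles) or with EtOH (ethanol), with 2 samples each. The series title gives the question, whether PRC1 activity keeps leukaemic cells in their identity, and the comparison that bears on it is OHT against EtOH.

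The file analysed here is the authors' own comparison, with 1 mean per group. Reads solved from those means came to 6255320 and 3841243 for EtOH libraries A and B and to 5687967 and 4509718 for OHT libraries A and B. The letters are arbitrary and do not follow the replicate numbers of the labels. Across 8378 transcripts with a mean of at least 50, Pearson's r of log2 reads was 0.948 between the EtOH libraries, 0.964 between the OHT libraries and 0.802 to 0.890 across treatments; transcripts are not independent replicates. No label says whether the samples of a group came from separate cultures or mice, so the p-values measure only the spread between these samples, which may be technical. No OHT-treated cells without the floxed allele were analysed here, so an effect of OHT itself is not separated from a loss of RING1B.

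Rnf2, the targeted gene (NM_011277), was not lower in the OHT samples. The authors' deposited table lists it at a mean normalised count of 636 with EtOH and 757 with OHT, a log2 fold change of 0.25 with an adjusted p of 1. Limma-voom on the solved reads gave 0.25 ± 0.21 (SE) with an adjusted p of 0.458. The labels do not say which part of the floxed allele is deleted, and a count over the whole transcript need not fall when some exons are lost, so this value does not check the labels. Ring1 (NM_009066), whose loss both groups share, had means of 68.3 and 122 in the authors' deposited table (adjusted p = 0.385). Reads of Ring1 and Cdkn2a were thus present although the stated genotype lacks both genes; which parts were deleted is not stated, so these counts do not check the genotype. Both Cdkn2a transcripts had close means in the authors' deposited table, 49.8 and 48.5 for NM_009877 and 29.9 and 31.6 for NM_001040654, each with an adjusted p of 1.

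Transcripts called higher with OHT had lower EtOH levels than those called lower, with median EtOH means of 41.6 and 555 in the authors' deposited table. Their median OHT means were 200 and 242. A split of calls by direction in part fixes such an EtOH difference in advance. Fstl1, a secreted follistatin-like glycoprotein, rose the most of the named genes, from a mean of 4.08 to 615 in the authors' deposited table (150.6-fold, adjusted p = 3.87e-47). Its limma-voom log2 fold change was 7.92 ± 0.70 (SE). Lipoprotein lipase (Lpl) rose 32.1-fold from 43.1 to 1383, and the macrophage scavenger receptor Marco 23.7-fold from 5.56 to 132, in the authors' deposited table. Mamdc2 fell the most of the named genes, 68.9-fold from 789 to 11.5 in the authors' deposited table (adjusted p = 4.06e-47). Its limma-voom log2 fold change was -6.54 ± 0.55 (SE). Col4a1, a basement-membrane collagen chain, fell 24.4-fold, the actin-binding protein gene Avil 10.2-fold and P2rx3, an ATP-gated ion channel, 6.70-fold by the authors' deposited table.

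Of 18061 RefSeq transcripts, 989 passed an adjusted p of 0.05 in the authors' deposited table, 654 of them higher with OHT (66.1%) and 335 lower. Calls of at least 4-fold numbered 363 higher against 28 lower, and of at least 10-fold 108 against 12, in the authors' deposited table. Other named rises in the authors' deposited table were the adhesion molecule Mcam (36.9-fold), the secreted chaperone clusterin (Clu, 32.2-fold), the chloride channel protein Clic6 (32.0-fold), the neuropeptide galanin (Gal, 28.8-fold), Stac2 (27.8-fold) and the mRNA-binding protein Igf2bp1 (22.5-fold). Foxl2, a forkhead factor of ovarian granulosa cells, had 1 solved read with EtOH and 234 with OHT, a read ratio of 221 (95% counting interval 39.3 to 8781). C1qb, a complement subunit, had 2 and 215, a ratio of 102 (27.8 to 845). Foxl2os rose 38.8-fold in the authors' deposited table, but it neighbours Foxl2 and the library kit does not mark strand, so reads of the pair may not be separable. Other named falls in the authors' deposited table were Angptl6 (23.4-fold), the cytochrome oxidase subunit Cox6a2 (20.7-fold), the helicase Recql4 (6.30-fold) and Snhg12, a host gene of small nucleolar RNAs (4.97-fold). Dus4l fell 4.81-fold, Cth, of cysteine synthesis, 4.57-fold, Cdr2l 4.53-fold and Extl1 4.21-fold in the authors' deposited table.

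All 989 called transcripts had both OHT libraries on one side of both EtOH libraries, as did 51.0% of all transcripts, where chance gives 33.3%. The number of lower calls hung on single libraries. Limma-voom on the solved reads called 1102 transcripts higher and 623 lower, including all 989 in the same direction. It called 1597 and 1075 without EtOH library A, 856 and 656 without EtOH library B, 795 and 133 without OHT library A, and 1046 and 372 without OHT library B. Some folds moved by over 1.5 times when 1 library was left out, with no change of direction. Without EtOH library A the limma-voom log2 fold change was 6.71 for Fstl1, 7.26 for Mcam, 7.97 for Clu, 5.66 for Lpl, 5.94 for Stac2 and 4.16 for Marco. Without EtOH library B it was 8.95 for Fstl1, 4.74 for Mcam, 4.10 for Clu and 4.27 for Stac2. Without OHT library A it was 4.69 for Foxl2os, 4.42 for Gal, -5.51 for Mamdc2, -3.54 for Cox6a2, -2.82 for Avil, -1.43 for Cth and -1.45 for Extl1. Without OHT library B it was 5.30 for Clu, -7.42 for Mamdc2, -6.66 for Cox6a2, -4.17 for Avil, -3.83 for Cth and -3.22 for Extl1.

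**Figure D1:**
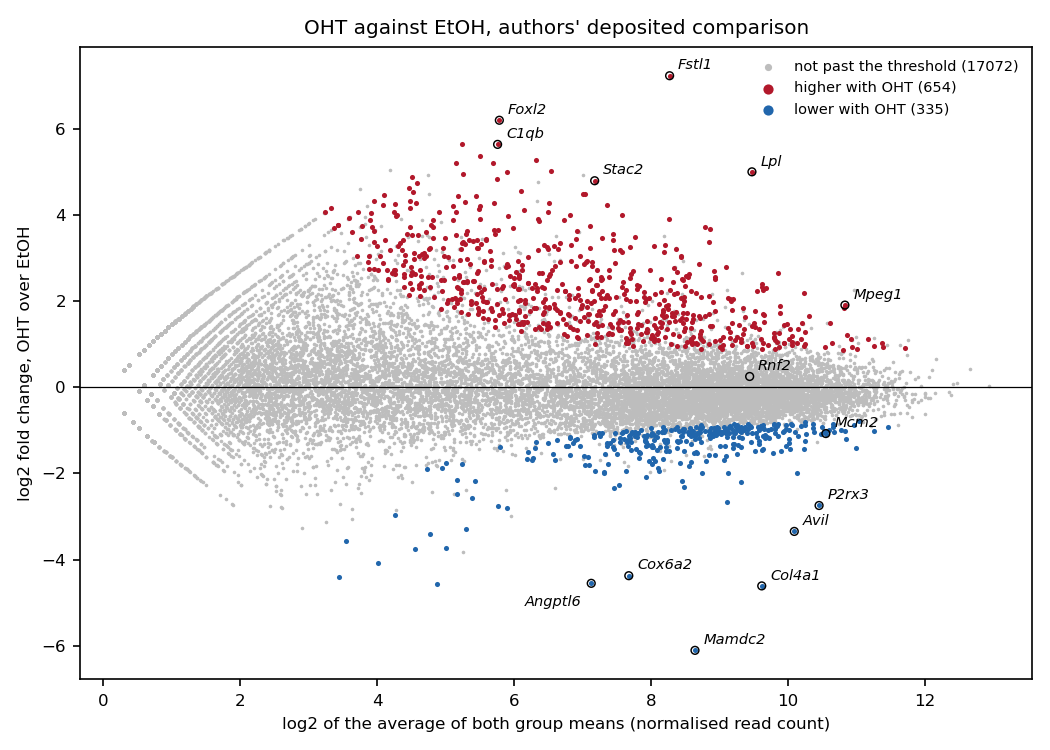
Each point is 1 of the 18061 transcripts, placed by the log2 of the average of both group means (horizontal axis, normalised read count) and the log2 fold change of OHT over EtOH (vertical axis) in the authors' deposited table, with red and blue for the 654 higher and 335 lower calls at an adjusted p under 0.05. The red points reach 7.23 (Fstl1) and spread over low to high expression, the blue points reach -6.11 (Mamdc2), and Rnf2 lies at 0.25.

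Genes were grouped in 35 lists fixed before the data were examined, and 56 of their 635 distinct measured members rose and 22 fell in the authors' deposited table. The median log2 fold change of 16 lists lay above, and that of 4 below, the central 95% of random lists matched on mean expression, where chance gives 1.75 outside it; lists that share members are not independent. On the solved reads, limma's camera called 18 lists at the preset correlation of 0.01. With an estimated correlation it called 0, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.454, and fry called 0, with 13 at an unadjusted p under 0.05 and a lowest adjusted p of 0.124. With 2 residual degrees of freedom these tests had little power, so a lost call does not show that a list was unchanged. In limma-voom the medians of 10 lists changed sign from the fit with all libraries when 1 library was left out. Of these, 1 (glycolysis) was among the 20 outside random lists. The histone median, -0.97 over 20 members and among the 4 below random lists, was 1.18 over the 6 members that limma-voom fitted. The position of a list among random lists therefore describes these libraries and does not allow for genes that vary together.

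Genes of embryonic patterning that Polycomb is known to silence outside their own tissues lay mostly above 0 with OHT, though few passed the test. Of 79 measured developmental transcription factors, 8 rose and none fell in the authors' deposited table, and 8 rose when adjusted over the list alone. Tbx15, a limb and skeletal T-box factor, rose 16.7-fold from 10.2 to 170.4, Sox21 8.25-fold from 6.81 to 56.2 and Zic2 7.69-fold from 15.3 to 118 in the authors' deposited table. The other risers were Foxl2, Lhx1, Otx1, Lhx2 and Gata4. A positive log2 fold change was found for 69 members, and the median of 1.08 in the authors' deposited table lay above all 10000 matched random lists, whose central 95% ran from 0.04 to 0.53. The camera call was lost with an estimated correlation (adjusted p = 0.454 with an estimated correlation). Many members lay near the floor: 24 had at most 3 reads in each group, and the median of the other 55 was 1.30, with the 6 members at 0 reads in EtOH set to their lower bound. Limma-voom called 18 members higher with all libraries, 10 without OHT library A, and 16 higher and 1 lower (Pax8) without EtOH library A. The limma-voom log2 fold change of Gata4 was 3.46, with 2.48 without EtOH library A and 4.35 without EtOH library B.

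Most Hox genes outside the HoxA cluster had positive log2 fold changes. Of 24 measured genes of the HoxB, HoxC and HoxD clusters, which pattern the body axis, 3 rose in the authors' deposited table, and 3 adjusted over the list alone. Hoxd13 rose 9.41-fold, from 8.53 to 80.2, and Hoxc9 11.8-fold, from 3.38 to 39.8, in the authors' deposited table. Hoxb7 had 1 solved read with EtOH and 47 with OHT, a ratio of 44.5 (95% counting interval 7.60 to 1793). Of the 24, 23 had a positive log2 fold change, and their median of 1.72 in the authors' deposited table lay above all matched random lists (camera adjusted p = 0.454 with an estimated correlation). It was 1.74 over the 20 members with more than 3 reads, with 4 members at 0 EtOH reads set to their bound. None of the 11 HoxA genes, the cluster that MLL fusions keep active, passed the test in the authors' deposited table or when adjusted over the list alone. Hoxa11 was listed at 349 and 405 and Hoxa7 at 336 and 252 in the authors' deposited table. The HoxA median was -0.22 and the mean 0.14, at percentile 18.9 of matched random lists of the authors' deposited values. The limma-voom HoxA median was -0.24, with -0.64 without OHT library A and 0.24 without OHT library B, and limma-voom called no HoxA gene with all libraries or in any omission of 1. In the GATA family, Gata3 (9.42-fold) and Gata4 (7.53-fold) rose, 2 of 6 in both adjustments, and Gata2 was listed at 2169 and 2230, in the authors' deposited table. The GATA median of 1.38 lay at percentile 98.5 in the authors' deposited table (camera adjusted p = 0.454 with an estimated correlation).

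Few Polycomb genes passed the test, and some were hardly measured on the 1 transcript that stood for them. Named after their values were seen, Ezh2 was listed at 19.1 and 13.3, Phc2 at 11.7 and 14.1 and Bcor at 3.85 and 2.51 in the authors' deposited table. A missing call there does not show an unchanged gene. Of 22 PRC1 subunit genes 1 rose, Rybp of variant PRC1 (1.96-fold), and of 11 PRC2 subunit genes 1 fell, Phf19 (2.42-fold), a Polycomb-like subunit, in both adjustments of the authors' deposited table. The medians of -0.16 and -0.43 lay at percentiles 25.5 and 3.26 of matched random lists of the authors' deposited values, inside the central 95%. Neither gene was called by limma-voom without OHT library A, where Rybp had a log2 fold change of 0.93 (adjusted p = 0.105) and Phf19 one of -1.23 (adjusted p = 0.0887). Without EtOH library A limma-voom called 4 PRC1 genes higher and 2 lower, and 2 PRC2 genes higher and 1 lower. The limma-voom PRC1 median was -0.10, with 0.18 without EtOH library A, -0.31 without EtOH library B, -0.30 without OHT library A and -0.02 without OHT library B. The limma-voom PRC2 median was -0.44, with -0.13 without EtOH library A and -0.25 without OHT library A.

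None of 22 genes of the MLL-fusion leukaemia programme passed the test, over all transcripts or adjusted over the list alone, in the authors' deposited table. Of the 22, Mecom and Men1, named after their values were seen, had at most 3 reads in each group. Cebpa, a myeloid transcription factor, was listed at 1097 and 1206 and the homeobox cofactor Pbx3 at 1040.3 and 923 in the authors' deposited table. Meis1 was listed at 41.2 and 51.7 and Hoxa9 at 55.6 and 47.7 in the authors' deposited table, and both were chosen after their values were seen. The programme's median of -0.23 lay at percentile 10.6 of random lists by the authors' deposited table. Its limma-voom median was -0.24, with 0.11 without EtOH library A and -0.45 without EtOH library B. Limma-voom called none of its members with all libraries, Six4 higher and Hmgb3 lower without EtOH library A, and Dot1l lower without EtOH library B. None of 8 cyclin-dependent kinase inhibitor genes passed the test in either adjustment of the authors' deposited table, with Cdkn2b at 394 and 496, Cdkn1b at 354 and 478 and the list median of 0.19 at percentile 72.9. None of 22 BCL2-family and apoptosis genes passed it either, with Mcl1 at 2413 and 3293, Bak1 at 1192 and 1164 and a median of 0.09 at percentile 81.5 in the authors' deposited table, while limma-voom called Birc3 and Bmf higher. Birc3 was not called by limma-voom without EtOH library B, where Bbc3 was called lower, or without OHT library A. Of 22 p53 target genes 3 rose in both adjustments, Plk2 (6.24-fold), Zmat3 (2.21-fold) and Phlda3 (1.86-fold), with a median of 0.33 at percentile 99.6, in the authors' deposited table. Camera did not call the p53 list at the preset correlation (adjusted p = 0.116), and the median of its limma-voom log2 fold changes was 0.32, with 0.21 without EtOH library B. Limma-voom called 4 p53 targets higher and Gadd45a lower (-0.96 ± 0.25 SE, adjusted p = 0.0290), and 3 higher and 2 lower (Bbc3 and Rrm2b) without EtOH library B. Cdkn1a, a p53 target and cell-cycle inhibitor chosen after its value was seen, was listed at 59.7 and 75.5 with an adjusted p of 1 in the authors' deposited table. The p53 median lay inside the central 95% of random lists not matched on mean, at percentile 89.7 of the authors' deposited values. The limma-voom log2 fold change of Plk2 was 3.01, with 4.47 without EtOH library A and 1.87 without EtOH library B. Phlda3 was not called by limma-voom without OHT library A (0.80, adjusted p = 0.241) or OHT library B (1.01, adjusted p = 0.0554).

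In the authors' deposited table, 25 of 26 S-phase, 24 of 24 G2/M and 23 of 23 ribosome biogenesis genes had a negative log2 fold change, and fewer of them passed the test. Of 26 S-phase genes, 8 fell in the authors' deposited table and 15 when adjusted over the list alone, and none rose. Dtl, of the replication-licensing ubiquitin ligase, fell 3.03-fold from 822 to 271 and the replicative helicase subunit Mcm2 2.10-fold from 2044 to 971 in the authors' deposited table. The ribonucleotide reductase gene Rrm1 fell 2.03-fold in the authors' deposited table. Limma-voom gave Dtl a log2 fold change of -1.61 ± 0.22 (SE). The S-phase median of -0.91 lay below all matched random lists of the authors' deposited values (camera adjusted p = 0.454 with an estimated correlation). Of 24 G2/M genes, the contractile-ring gene Anln (2.07-fold) and the kinetochore gene Ndc80 (2.09-fold) fell in the authors' deposited table, and 4 fell adjusted over the list alone. The G2/M median was -0.50, at percentile 0.07 in the authors' deposited table (camera adjusted p = 0.454 with an estimated correlation). Of 23 ribosome biogenesis and MYC target genes, 7 fell in the authors' deposited table, 10 fell adjusted over the list alone, and none had a positive log2 fold change. Utp20, of the small-subunit processome, fell 2.89-fold from 1309 to 453, the RNA polymerase I subunit Polr1b 2.14-fold, the pseudouridine synthase Dkc1 2.11-fold and Wdr43 2.04-fold in the authors' deposited table. Their median of -0.71 lay below all random lists of the authors' deposited values (camera adjusted p = 0.497 with an estimated correlation).

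Fewer of these genes were called without OHT library A, as with lower calls in general, while the medians moved less. That fit takes its spread from the EtOH libraries alone. Their median absolute log2 difference was 0.323, against 0.206 between the OHT libraries. The fit without OHT library B takes its spread from the same EtOH libraries, so that spread alone does not account for the lost calls. With 1 residual degree of freedom, lost calls still need not mean a lost effect. Limma-voom called 15 S-phase, 5 G2/M and 10 ribosome biogenesis genes lower with all libraries, 3, 0 and 1 without OHT library A, and 9, 2 and 12 without OHT library B. It called 8 G2/M genes without EtOH library A and 6 ribosome biogenesis genes without EtOH library B. Without OHT library A it did not call Mcm2 (log2 fold change -0.94, adjusted p = 0.0653), Rrm1 (-0.88, 0.0930), Anln (-0.99, 0.124), Ndc80 (-0.99, 0.182), Polr1b (-0.80, 0.189), Dkc1 (-0.82, 0.142) or Wdr43 (-0.87, 0.0993). Nor did it call Ndc80 without OHT library B (-1.12, 0.0673). The limma-voom medians of the S-phase, G2/M and ribosome biogenesis genes were -0.92, -0.51 and -0.69 with all libraries. They were -0.84, -0.51 and -0.42 without OHT library A and -0.98, -0.53 and -0.95 without OHT library B. All were negative in each of the 4 omissions. The fall of ribosome biogenesis genes was thus smaller in OHT library B than in OHT library A.

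Lists that mark RNA quality were read beside these changes. Immediate-early genes, given further below, were also fixed as such a list, and their median of 0.87 lay above all random lists of the authors' deposited values. None of 34 ribosomal protein genes passed the test in either adjustment of the authors' deposited table, with Rpl4 at 2650 and 2315, Rpl3 at 2347 and 1997 and a median of -0.20 at percentile 11.4. A negative log2 fold change was listed for 33 of them, and the median of all transcripts with a mean of at least 100 was -0.14, in the authors' deposited table. The EtOH libraries differed in ribosomal protein genes by a median log2, B minus A, of 0.63, and their limma-voom median was -0.18, with -0.50 without EtOH library A and 0.13 without EtOH library B. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had a median of -0.97 over 20 members, below all random lists, by the authors' deposited table. The 2 histone genes that passed, in both adjustments, went up, Hist1h1c 2.58-fold and Hist1h2bc 3.18-fold, in the authors' deposited table. Camera on the 6 members with enough reads also pointed up, a call at the preset correlation that was lost with an estimated one (adjusted p = 0.628 with an estimated correlation). Without EtOH library A limma-voom called 2 histone genes higher and 2 lower (Hist1h1d and Hist1h1e). The median log2 difference between the EtOH libraries in histone genes, B minus A, was 1.36.

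Of 20 unfolded-protein and integrated stress response genes, 3 fell and 1 rose in the authors' deposited table, and 4 fell and 1 rose adjusted over the list alone. Trib3 fell 3.95-fold from 1797 to 455, the transcription factor Ddit3 2.56-fold and asparagine synthetase (Asns) 2.04-fold, and Atf3 rose 2.84-fold, in the authors' deposited table. The median of -0.16 lay at percentile 34.5 in the authors' deposited table. In limma-voom the log2 fold change of Trib3 was -2.12, with -1.51 without OHT library A, where Ddit3 (-1.09, adjusted p = 0.0594) and Asns (-0.75, 0.193) were not called.

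Of the monocyte and macrophage markers, 23 of 25 had a positive log2 fold change in the authors' deposited table. The test was passed by 10 that rose and none that fell in the authors' deposited table, and 13 rose adjusted over the list alone. The scavenger receptor Msr1 rose 4.55-fold from 146 to 664 and the macrophage perforin Mpeg1 3.76-fold from 769 to 2888 in the authors' deposited table. C1qb, C1qc, C1qa, Maf, Irf8, Lgmn and Klf4 were also among the risers. Limma-voom gave Msr1 a log2 fold change of 2.20 ± 0.30 (SE). The median of 1.91 lay above all matched random lists of the authors' deposited values (camera adjusted p = 0.454 with an estimated correlation). The EtOH libraries themselves differed in these markers, with a median log2 difference, B minus A, of -0.91 against -0.23 between the OHT libraries. The limma-voom log2 fold change of Mpeg1 was 2.03, with 2.73 without EtOH library A and 1.39 without EtOH library B. Limma-voom called 14 markers higher with all libraries and 14 to 17 in the 4 omissions of a library, and 1 lower (Apoe) without EtOH library A.

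Of 23 neutrophil maturation markers, 4 rose in both adjustments of the authors' deposited table: the chemokine receptor Cxcr2 (2.79-fold, from 624 to 1743), lysozyme Lyz2 (2.41-fold), and the proteases Mmp8 (1.92-fold) and Mmp9 (1.90-fold). The neutrophil median of 0.63 lay at percentile 99.99 of random lists in the authors' deposited values (camera adjusted p = 0.497 with an estimated correlation). Limma-voom called 5 members higher and none lower, 10 higher without OHT library B, and 4 higher and 1 lower (Ltf, chosen after its values were seen) without EtOH library A or OHT library A. The median of their limma-voom log2 fold changes was 0.63, with 0.34 without EtOH library A and 0.10 without OHT library A. Limma-voom did not call Mmp8 without EtOH library B (0.74, adjusted p = 0.0664) or OHT library B (0.81, adjusted p = 0.0589). Of 14 primary granule and promyelocyte genes, Igsf6 rose 2.06-fold and the repressor Gfi1 fell 4.44-fold, in both adjustments, with a median of -0.24 at percentile 16.1, in the authors' deposited table. Igsf6 was not called by limma-voom without OHT library A (0.82, adjusted p = 0.165), nor Gfi1 without OHT library B (-1.76, adjusted p = 0.0854). The limma-voom median of the granule list was -0.19, with -0.55 without EtOH library A, 0.15 without EtOH library B and -0.04 without OHT library A.

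Of 15 dendritic cell markers, the integrin Itgax rose 6.41-fold from 90.1 to 577 and the transcription factor Batf3 9.10-fold from 4.08 to 37.2 in the authors' deposited table, and 5 markers rose adjusted over the list alone. The median of 1.82 lay above all random lists of the authors' deposited values (camera adjusted p = 0.454 with an estimated correlation). It was 2.04 over the 13 members with more than 3 reads, with the 2 members at 0 EtOH reads set to their bound. Limma-voom called 6 dendritic markers higher, and 3 without EtOH library B or without OHT library B. The log2 fold change of Batf3 was 3.86 in limma-voom, with 2.65 without EtOH library A and 4.89 without EtOH library B. None of 14 mast cell and basophil markers passed the test in either adjustment of the authors' deposited table, where Gata2 was at 2169 and 2230 and the mast cell protease Cpa3 at 1879 and 1935. Their median of 1.07 lay at percentile 99.99 in the authors' deposited table (camera adjusted p = 0.628 with an estimated correlation). OHT library B held more of them than OHT library A, with a median log2 difference, B minus A, of 1.57 against -0.59 between the EtOH libraries. Limma-voom called 1 mast cell marker higher (Prss34), 5 without OHT library A and 0 without EtOH library B. The limma-voom median of the mast cell list was 1.08, with 1.69 without OHT library A and 0.39 without OHT library B. None of 8 eosinophil markers passed it in either adjustment, with Prg2 at 992 and 586, Epx at 482 and 146 and a median of -0.40 at percentile 6.00 in the authors' deposited table. Limma-voom called Epx lower with all libraries (-1.60 ± 0.36 SE, adjusted p = 0.0176) and in each omission of a library, and 3 eosinophil markers lower without EtOH library A (Epx, Prg2 and Prg3).

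Single markers of lineages outside the myeloid series rose. Of 17 T-cell markers, Thy1 (16.0-fold, from 22.4 to 358), the transcription factor Tcf7 (4.08-fold) and Gata3 rose in both adjustments of the authors' deposited table. The T-cell median of 1.05 lay at percentile 99.9 in the authors' deposited table (camera adjusted p = 0.454 with an estimated correlation). None of 12 B-cell markers passed in either adjustment of the authors' deposited table, with Il7r at 152 and 448, Bank1 at 60.8 and 166 and a median of 0.62 at percentile 97.6. None of 6 NK-cell markers passed either, with Cd244 at 384 and 505, granzyme B (Gzmb) at 46.8 and 538 and a median of 1.35 at percentile 99.7, in the authors' deposited table. Camera called neither list at the preset correlation (adjusted p = 0.0639 and 0.111) or with an estimated one (adjusted p = 0.454 for both with an estimated correlation). Limma-voom called Bank1 and Gzmb higher, neither of them without EtOH library B, and Il7r in place of Bank1 without OHT library A. The limma-voom median of the NK-cell list was 1.26, with 2.09 without EtOH library B. Libraries A and B had 77.1 and 14.3 normalised reads of Gzmb with EtOH and 208 and 865 with OHT. For Il7r they had 257 and 44.3 with EtOH and 198 and 697 with OHT, so the treatments overlapped. Of the 12 B-cell markers, 6 had at most 3 reads in each group, and the median of the other 6 was 1.51. Of 16 megakaryocyte and platelet markers, the platelet chemokine Pf4 rose 5.69-fold in both adjustments of the authors' deposited table. Their median of 1.12 lay above all random lists of the authors' deposited values (camera adjusted p = 0.454 with an estimated correlation). Over the 15 members with more than 3 reads the median was 1.47, and 0.76 with the 1 member at 0 EtOH reads set to its bound. Limma-voom called 4 megakaryocyte markers higher, and 1 without EtOH library B, and their limma-voom median was 0.65, with 1.0 without EtOH library A.

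Of 20 stem and progenitor markers Procr (4.17-fold) and Tal1 (9.85-fold) rose, and of 11 erythroid markers carbonic anhydrase Car2 (10.5-fold) and the erythropoietin receptor Epor (9.32-fold), in the authors' deposited table. Of 12 marrow stroma markers Col1a1 (5.69-fold) and Acta2 (5.39-fold) rose, and of 11 endothelial markers Flt1 (2.96-fold), in the authors' deposited table. Adjusted over the list alone the same numbers rose, and 1 stem and progenitor marker, Lmo2, fell. The 4 medians of 0.19, 0.55, 0.52 and 0.82 lay inside the central 95% of random lists of the authors' deposited values, at percentiles 62.2, 83.7, 77.8 and 96.9. The endothelial one lay at 99.0 of random lists not matched on mean. Over members with more than 3 reads, those at 0 reads in a group set to their bound, the 4 medians were 0.01, 0.92, 0.65 and 1.65. Camera called the erythroid list up at the preset correlation, a call lost with an estimated one (adjusted p = 0.454 with an estimated correlation). Its limma-voom median was 0.95, with 1.75 without EtOH library A and 0.59 without OHT library B. That of the stem and progenitor list was -0.24, with 0.58 without EtOH library A and -0.22 without EtOH library B. It was 0.32 without OHT library A and -0.39 without OHT library B. None of 8 germline genes passed in either adjustment of the authors' deposited table, with Tdrkh at 322 and 231, Zcwpw1 at 40.5 and 47.4 and a median of -0.23 at percentile 11.7. Procr had a limma-voom log2 fold change of 2.25, with 3.35 without EtOH library A and 1.40 without EtOH library B, and Tal1 one of 3.25, with 3.93 without EtOH library A. Col1a1 was not called by limma-voom without OHT library A (2.59, adjusted p = 0.0572).

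Some interferon-stimulated and immediate-early genes rose. Of 23 interferon-stimulated genes, 5 rose in both adjustments of the authors' deposited table, the nucleic-acid sensor Zbp1 (5.12-fold, from 20.9 to 107), viperin (Rsad2, 16.7-fold, from 4.03 to 67.3), Cmpk2 (4.03-fold), Dhx58 (2.15-fold) and Rtp4. Their median of 1.08 lay at percentile 99.9 in the authors' deposited table (camera adjusted p = 0.454 with an estimated correlation). Limma-voom did not call Cmpk2 without EtOH library A (1.60, adjusted p = 0.0646) or OHT library A (1.82, 0.0905), nor Dhx58 without OHT library A (1.03, 0.161). Of 18 immediate-early genes, which also respond to the handling of cells, 5 rose in the authors' deposited table and 7 adjusted over the list alone. Fos rose 5.43-fold from 99.96 to 543, Jun 3.17-fold, Dusp1 2.55-fold and Ier3 2.06-fold in the authors' deposited table, beside Atf3. Their median of 0.87 lay above all random lists of the authors' deposited values (camera adjusted p = 0.454 with an estimated correlation). Limma-voom called 7 immediate-early genes higher, and 13 higher and 2 lower (Ier2 and Klf2) without EtOH library A. The limma-voom log2 fold change of Atf3 was 1.56, with 2.33 without EtOH library A and 0.97 without EtOH library B.

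None of 18 cholesterol synthesis genes passed the test in either adjustment of the authors' deposited table, with Srebf2 at 1952 and 1986. Limma-voom called Insig1 and Nsdhl higher, and 0 members without OHT library A or OHT library B. A positive log2 fold change was listed for 17 of them, and the median of 0.31 lay at percentile 99.6, and at 85.5 of random lists not matched on mean, in the authors' deposited table (camera adjusted p = 0.454 with an estimated correlation). Of 19 glycolysis and hypoxia genes Egln3, a prolyl hydroxylase, rose 1.90-fold in the authors' deposited table, and 3 genes rose adjusted over the list alone. The median of 0.25 lay at percentile 98.2, and at 80.8 of random lists not matched on mean, in the authors' deposited table (camera adjusted p = 0.454 with an estimated correlation). Egln3 was not called by limma-voom without OHT library A (0.89, adjusted p = 0.105), and the limma-voom median of the list was 0.17, with 0.07 without EtOH library A, 0.31 without EtOH library B and a change of sign without OHT library B.

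**Figure D2:**
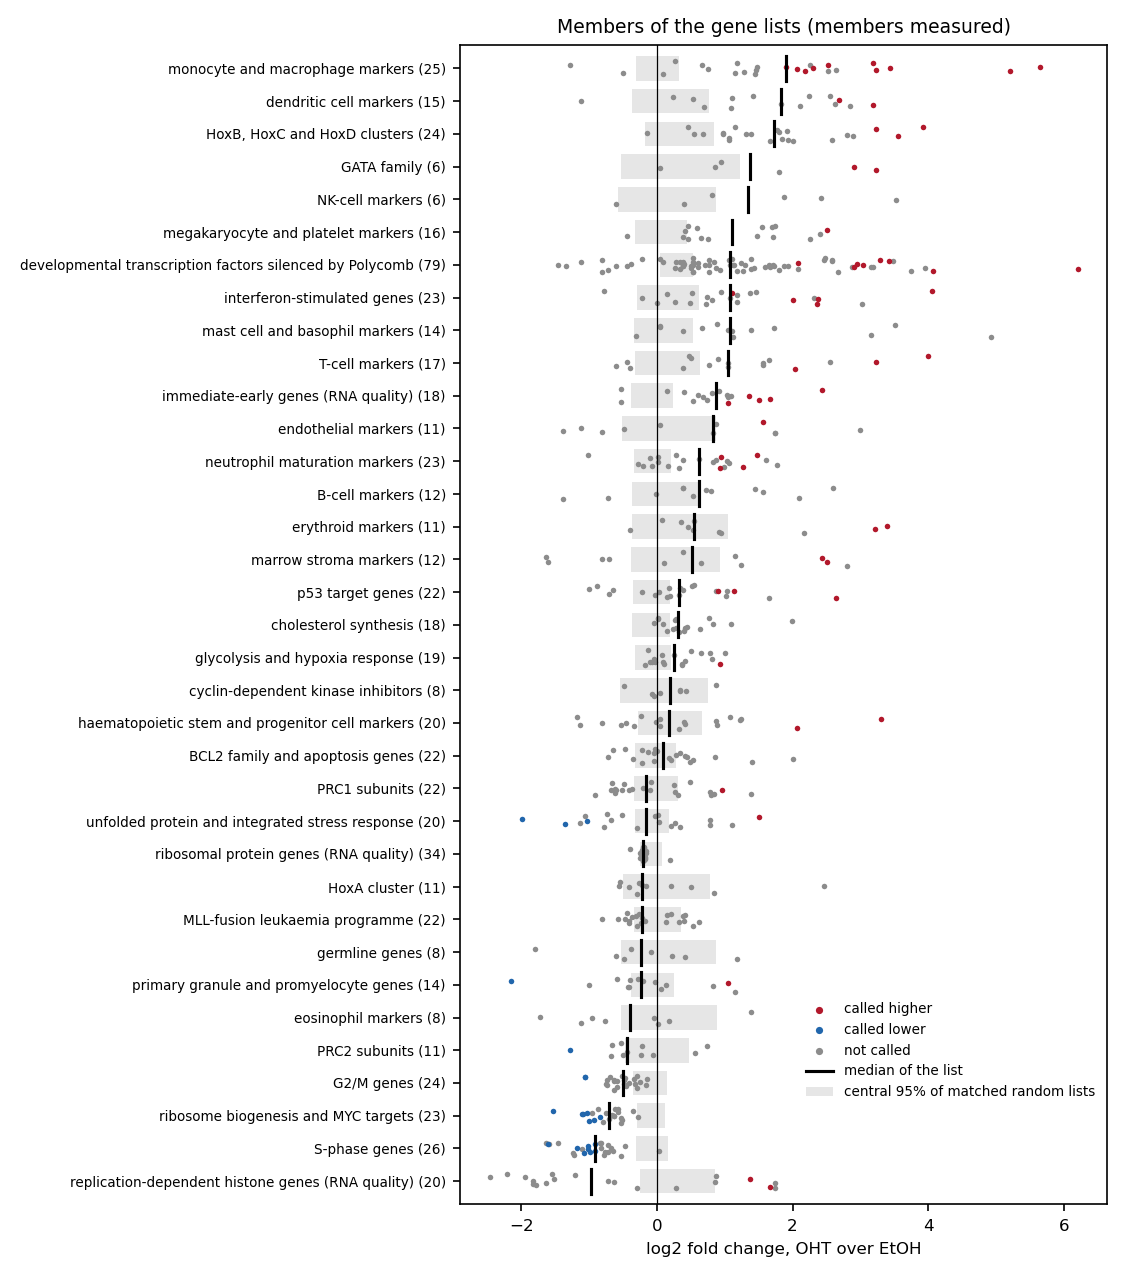
Each point is the log2 fold change of OHT over EtOH (horizontal axis) of 1 member of a gene list in the authors' deposited table, red or blue where the member passed an adjusted p of 0.05, with 1 row per list and the number of members measured in parentheses. Black bars are list medians and grey bands the central 95% of 10000 random lists matched on mean expression; of these medians over all members, the monocyte and macrophage one (1.91) is the highest and the S-phase (-0.91) and histone (-0.97) ones are the lowest.

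**Figure D3:**
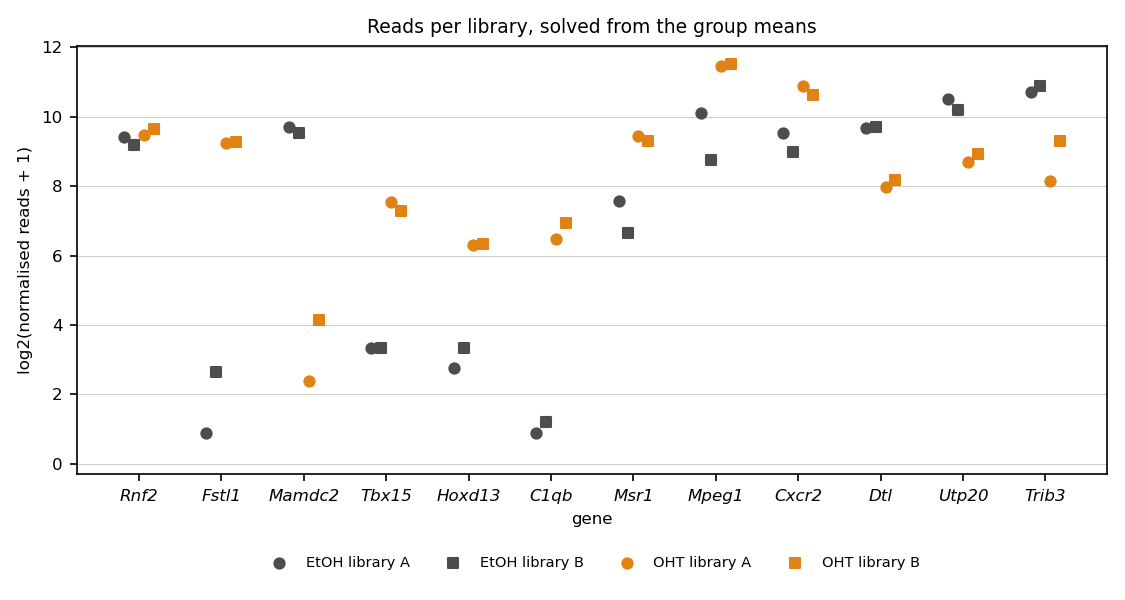
Points are log2(normalised reads + 1) per library for 12 genes, from the reads solved from the group means divided by the size factors solved with them, with grey for EtOH, orange for OHT, circles for library A and squares for library B of each group. Both OHT libraries lie on one side of both EtOH libraries for all 12 genes, with the narrowest gap for Rnf2, where EtOH library A had 687 and OHT library A 716 normalised reads.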

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

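Of the alternatives in this part, limma-voom on the solved reads, its scalings and filters, the omission of single libraries, camera, fry and 1 transcript per symbol were chosen only after the result was seen. The authors' deposited table gave 654 transcripts higher, 335 lower, 78 list members and 20 lists outside random lists. With an adjusted p under 0.01 these became 432 higher, 163 lower and 48 list members, since the threshold alone is stricter. With a mean of at least 100 and the adjusted p recomputed, 417 were higher, as transcripts of low mean were left out. Limma-voom called 1102 higher, 623 lower and 129 list members; the cause was not tested. Camera with an estimated correlation called 0 lists (1 at an unadjusted p under 0.05) and fry 0 (13 at an unadjusted p under 0.05), against 18 by camera at the preset correlation. These tests allow for correlation among genes, but they rest on 2 residual degrees of freedom. The dendritic cell call was lost although its estimated correlation of -0.07 lay below the preset 0.01. Correlation alone thus does not account for the lost calls. Leave-one-out limma-voom fits gave 795 to 1597 higher, 133 to 1075 lower and 82 to 180 list members; the cause of the spread was not tested. Each such fit leaves 1 sample in an arm and 1 residual degree of freedom, and the lone sample is assumed to vary like the other arm.

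The other alternatives stayed within 1.5 times: a 2-fold minimum, a mean of at least 10, 1 transcript per symbol, unmatched random lists (18, with p53 targets, cholesterol synthesis and glycolysis no longer outside and endothelial markers newly outside), and in limma-voom upper-quartile scaling (1304 higher, 471 lower), total-read scaling, no filter and at least 50 reads. Of the comparisons of named transcripts with an alternative, 1136 kept direction and side of the threshold, 28 kept direction but no longer passed and 5 newly passed. The other 2, both uncalled and near 0, changed sign in limma-voom, Gata2 to -0.0679 and Cpa3 to -0.0391; the cause was not tested. Rnf2 stayed positive and uncalled under each alternative run. No paired analysis was possible because the deposited table holds 1 mean per group and the solved libraries carry no replicate numbers. Alternatives set beforehand that need deposited counts or normalised values per sample were not run: other count tests and their normalisations, the replicate number as a term, and the pseudocount. Depth of 3841243 to 6255320 reads per library limits genes near the floor, and 2-fold changes were recovered in 22% of simulated cases against 94% at 4-fold. The simulation had a set dispersion of 0.05 and few changed transcripts, so these shares need not hold for the real comparison.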

Other observations

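The tests of gene families, of the B-cell markers and of macrophage against other markers, the S-phase difference without single libraries, and the floor condition on receptor genes, were chosen only after the result was seen, as was the limma-voom fit behind the splits. Toll-like receptor genes, sensors of microbial products, were over-represented among rises. Of 11 measured, Tlr7, Tlr9, Tlr5, Tlr13 and Tlr2 rose in the authors' deposited table, against 3.94% of all genes (Fisher's exact test, adjusted p = 0.0184 over 518 tests of 259 families with at least 8 genes). Of 25 measured methyltransferase-like genes, Mettl16, Mettl1, Mettl4, Mettl5 and Mettl22 were called lower in the authors' deposited table, against 2.03% of all genes (Fisher's exact test, adjusted p = 0.0326). Matrix metalloproteinase genes had 5 of 17 higher, Mmp13, Mmp9, Mmp8, Mmp27 and Mmp11, in the authors' deposited table (Fisher's exact test, adjusted p = 0.0674). Genes of a family are not independent of each other, and these tests were not matched on expression. Transcripts called lower had a median EtOH mean of 555, so expression alone may raise a family's share of such calls.

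Libraries of the same treatment differed in some markers, named here after their values were seen. OHT library A and OHT library B had 78.1 and 419 normalised reads of the basophil protease Prss34, 85.7 and 325 of Mcpt8, 61.3 and 298 of Tpsb2 and 307 and 1166 of Il1rl1. EtOH library A and EtOH library B had 1197 and 189 of Gpnmb, 236 and 53.4 of Lgmn and 26.5 and 3.91 of Maf. The granule gene Mpo had 18.2 and 160 in the EtOH libraries and 351 and 50.2 in the OHT libraries, and Elane 110 and 527 against 504 and 160. Transcripts with reads in both OHT libraries and none in either EtOH library numbered 581, against 105 the other way.

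Developmental transcription factors silenced by Polycomb had a median log2 fold change of 1.08 in the authors' deposited table (95% bootstrap interval 0.61 to 1.39), with 8 of 79 called higher and the camera call lost with an estimated correlation (camera adjusted p = 0.454). Bootstrap intervals in this part resample the genes of a list as if independent and leave out the spread between libraries. A general rise of lowly expressed genes would leave the list among random lists matched on mean, and its median lay at percentile 100 of them. Background reads from silent loci in the OHT libraries stay open: 84 olfactory and vomeronasal receptor genes had a median of 0.39, but 61 of them had at most 3 reads in each group, where the read added to each count fixes the fold. A release of Polycomb target genes by a loss of RING1B, which the Rnf2 counts do not check, is a hypothesis left open beside it. An effect of OHT itself was not tested, since each OHT sample also carried the floxed allele.

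Monocyte and macrophage markers had a median log2 fold change of 1.91 in the authors' deposited table, with 10 of 25 called higher and the camera call lost with an estimated correlation (camera adjusted p = 0.454). Macrophages beside unchanged leukaemic cells would lower S-phase and MLL-programme genes alike if macrophages expressed neither set, which was not tested. The S-phase median minus the programme's was -0.69 (95% bootstrap interval -1.18 to -0.51). In limma-voom it was -0.68, with -0.32 (-0.65 to -0.07) without EtOH library B and -1.16 without EtOH library A. The level of the programme's 22 genes in macrophages was not tested. The S-phase difference therefore cannot decide whether macrophages were present. A lower share of leukaemic cells would raise the markers of every other cell type alike. Over members with more than 3 reads the macrophage median of 1.91 exceeded the eosinophil median of -0.04 (7 members) by 1.95 (0.07 to 3.79, widened for the 9 lists compared). The eosinophil list was the 1 list of 9 that stood apart. Its members Prg2 and Epx had means of 992 and 482 with EtOH, so leukaemic cells may make these transcripts themselves. The comparison therefore cannot decide. That comparison replaced 2 with B-cell markers alone, which gave 1.29 (0.02 to 2.0) over all members and 0.40 (-0.64 to 1.39) over members with more than 3 reads. Carried-over marrow cells of several types stay open. The 3 B-cell markers with an OHT mean of at least 10 and above their EtOH mean were Il7r, Bank1 and Cd79b. Each was already above 10 with EtOH and none was called, so their count cannot decide. A change of cell identity, a hypothesis, stays open too.

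Genes called higher lay next to each other in the genome more often than permuted calls of like expression. There were 50 adjacent pairs of genes that do not overlap, against a mean of 22.2 and a 95th percentile of 30 in 10000 permutations (permutation p = 0.0001, the smallest they can give), in the gene order of GRCm38.p6 with 93.5% of genes placed. Tandem copies of related genes are not the whole source, since 37 pairs with unlike symbols remained, against a mean of 20.4 in the permutations (permutation p = 0.0003), Rsad2 with Cmpk2, Cav2 with Met and Ephb2 with C1qb among them, named after their values were seen. Genes called lower formed 5 pairs against a mean of 6.26 in the permutations (permutation p = 0.761). That neighbouring genes change together, through shared chromatin or through transcription that runs on past a gene's end, may explain the 50 pairs, and these were not tested apart.

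The limma-voom fit called 1725 transcripts. The 4 libraries have 3 splits into groups of 2, too few for a share under 0.05. Of the 3 splits, 1 gave as many calls, the real one, and the highest other gave 0. Each other split put 1 EtOH and 1 OHT library on each side, so a treatment difference became spread within its groups. The 0 therefore does not show how many calls chance would give.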
